A study of Mus musculus with 14 samples.

How the data were processed

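RNA of MC3T3-E1 mouse osteoblast-line cells was sequenced in 14 libraries, grouped by condition and day as the labels give them. Per the labels' protocols, the RNA was treated with DNase, polyadenylated RNA was selected with oligo(dT) beads, and strand-specific libraries were made from it. Per the submitters' processing notes, bcl2fastq, TopHat2 and edgeR were used with the genome build GRCm38; their versions and roles, the counting tool and its strand setting, and the annotation release are not given in the sources used here. The authors deposited raw read counts per gene for 24346 genes and RPKM values for 24340 genes, both with 1 column per library. In 5060 genes compared, the deposited RPKM values equalled the counts scaled by 1 factor per gene and 1 per library, within 1.90%. The tests were run on the counts, and the RPKM values served as an alternative.

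Gene identifiers were matched to the GENCODE release 21 annotation of GRCm build 38, which gave a position for 24181 of them and none for 165. This release may differ from the authors', and coordinates, exon lengths and GC contents come from it. Genes that overlap, lie antisense to each other or have near-identical copies may share reads, since the counting is not given. Bglap is named as uncertain for this reason.

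Genes with at least 10 counts in at least 2 libraries were tested, 13130 in all, and 11216 were left out as too low. Counts were scaled by the trimmed mean of M values, and CPM are counts relative to library size on that scale. A model with a mean for each of the 8 groups was fitted to all 14 libraries in edgeR 4.0.16 (R 4.3.3, robust quasi-likelihood F test, 6 residual degrees of freedom), so that all groups share 1 estimate of the spread. Each p was adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were the difference between the conditions averaged over days 0, 3 and 5, at each of the 4 days, the changes with time within a condition, and a joint test of whether the difference varied between days 0, 3 and 5. The groups, these tests, the gene lists and the rule for the genes named were fixed before the data were examined. Intervals of Macf1 are at the 95% level from the fit.

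Lists of genes (38, fixed with the design) were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01. The same test with an estimated correlation, and fry, stood beside it. Per list, calls were also counted with the adjustment over the list alone. At day 10, with 1 library per condition, lists were described by the percentile of their median among 10000 random lists of equal size matched on expression.

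The genes named were Macf1 and 16 others fixed by name, the 10 largest rises and 10 largest falls averaged over the days and the 5 of each for single days and for control day 5 against day 0, the 10 smallest p of the test between days, and up to 4 called members of each list that was called or had at least 3 called members. Those chosen by size had an adjusted p under 0.05, a mean of at least 5 CPM and an official symbol, and, for the average over days, the same direction at each. Where a library of a compared group held 0 to 3 counts, levels or counts stand beside or in place of a fold change.

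Replicates were compared before averaging. Chi-square statistics per degree of freedom were 12.9 to 39.6 in 5 pairs and 178.5 in the control pair of day 3, so that every pair differed by more than sampling noise and none was counted as 1 library. Whether the replicate numbers pair libraries across conditions was checked by the correlation of same-numbered libraries' deviations from their group means across genes, which was 0.234, 0.141 and 0.228 at days 0, 3 and 5. Each is over 0.1, but groups of different days gave 0.0393 to 0.319 as well. The check therefore cannot tell a pairing within days from a difference between replicate numbers that the days share. The main fit used no block, and fits with the number as a block were run as alternatives. Values with the number as a block are given where they change a call or a count by over 1.5 times.

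The tests whose recovery is given here were first run on simulated data for 13130 genes, with 100 genes changed 2-fold and 100 changed 4-fold. Means, dispersions and library sizes were estimated on the real libraries, with control day 3 replicate 2 among them, so that its spread entered the dispersions of all simulated libraries. For control day 5 against day 0 and for the test between days, the simulated means did not differ between days. The changes were then set only in control at day 5. Changed genes were drawn only from those with a mean count above what the filter requires, so the rates do not cover the lowest genes tested. No simulated library stood apart as control day 3 replicate 2 did. Recovery was not computed for control from day 0 to days 3 and 10 or for the libraries labelled knockdown from day 0 to day 5. For the average over days 0, 3 and 5, edgeR recovered 88% of the 2-fold and 97% of the 4-fold changes and called 15 unchanged genes. Single days 0, 3 and 5 gave 18% and 87%, 17% and 87%, and 18% and 88%. Day 10 gave 2% and 45%, control day 5 against day 0 gave 14% and 90%, and the test between days gave 1% and 43%.

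The alternatives were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or a mean of at least 50 counts, the DESeq2 1.42.0 Wald test, limma-voom, edgeR without robust estimation, limma on log2(RPKM + 1) and log2(RPKM + 0.1), the replicate block, an additive model, other sets of libraries, and leaving out each of the 12 replicated libraries in turn. For the test between days, the likelihood ratio test of DESeq2 took the place of its Wald test. Without day 3, removal of chromosome medians and removal of a trend with gene length were added after the data were seen. The libraries held 8044687 to 23301514 counts, so that a gene at 1 CPM rests on few reads. Nothing in the count table was left out except genes under the filter, and reads were not analysed here.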

Results

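Polyadenylated RNA was sequenced from MC3T3-E1 cells, a mouse line of osteoblast precursors, in 14 libraries. The labels divide them into control and MACF1 knockdown at days 0, 3, 5 and 10, with 2 libraries per group at days 0, 3 and 5 and 1 library per group at day 10. The sources used here do not say from what event the days are counted. The series asks whether MACF1, a large protein that links actin filaments to microtubules, furthers osteoblast differentiation through Wnt signalling. The control libraries held 16228425 and 14166742 counted reads at day 0, 15419979 and 8044687 at day 3, 18128624 and 12590033 at day 5, and 20124104 at day 10. Those labelled knockdown held 18089569 and 13846849, 19094812 and 13096527, 23301514 and 14499406, and 17737610. The series' design text calls the pairs biological replicates. No source used here says whether they came from separate cultures, so that p-values measure the spread between these libraries, which may be technical.

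Macf1 (ENSMUSG00000028649.15, minus strand of chromosome 4, 123349633 to 123684360, GRCm38) was read first in every library, as a check of the labels. Its level in control was 154 and 160 CPM (counts relative to library size, scaled by trimmed mean of M values) at day 0, 189 and 55.2 CPM at day 3, 176 and 205 CPM at day 5, and 196 CPM at day 10. In the libraries labelled knockdown it was 157 and 163, 172 and 170, 169 and 181, and 129 CPM. The mean log2 fold change over days 0, 3 and 5 was 0.13 (SE 0.24, 95% confidence interval −0.40 to 0.66; adjusted p = 0.724, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The libraries labelled knockdown lay below both control libraries of their day at 0 of the 3 replicated days. Control day 3 replicate 2 held 376 Macf1 counts, and without it the log2 fold change was −0.08 (interval −0.21 to 0.05; adjusted p = 0.277). Without control day 3 replicate 1 it was 0.51, but that fit keeps the low replicate 2 as the only control library of day 3. At day 10 the difference of the 2 single libraries was −0.60 (adjusted p = 0.827). It passed as lower without control day 3 replicate 2 (−0.60, interval −0.89 to −0.31; adjusted p = 0.0112), with 1 library per condition. The labels were kept, and every direction below is that of the libraries labelled knockdown relative to control, for which no fall of Macf1 passed at days 0, 3 and 5 (log2 fold changes of 0.03, 0.48 and −0.12; adjusted p = 0.983, 0.447 and 0.918). Dst, which encodes the other mammalian spectraplakin, had a log2 fold change of 0.44 (SE 0.17, adjusted p = 0.0788), with values of 0.65 and 0.30 (adjusted p = 5.83e-05 and 0.0116) without control day 3 replicate 1 or 2.

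**Figure D1:**
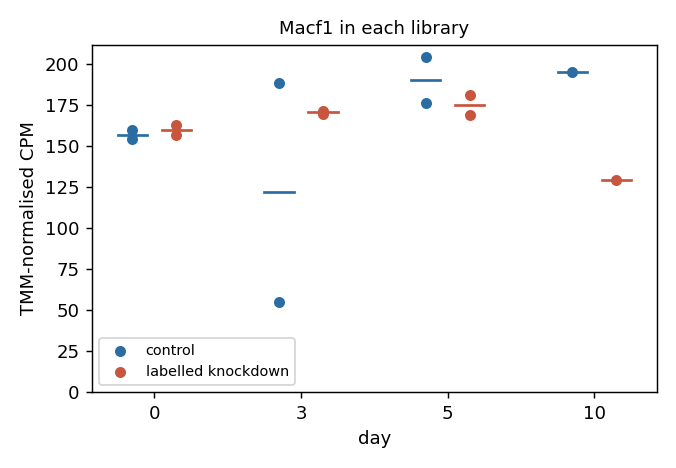
Macf1 in each of the 14 libraries, in CPM (vertical axis) by day (horizontal axis), for control and for the libraries labelled knockdown. Control day 3 replicate 2 stood at 55.2 CPM, and the other 13 libraries lay between 129 and 205 CPM.

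Control day 3 replicate 2 stood apart from the other libraries. Its 8044687 counts were 0.522 times those of its replicate. Of them 18.7% fell on cytoplasmic ribosomal protein genes (5.39% to 11.1% in the others). The log2 CPM of the pair correlated at 0.924 across genes (0.987 to 0.989 in the other 5 pairs; genes are not independent replicates). The difference of the pair followed exon length, with a Spearman correlation of −0.404 across genes against −0.030 to 0.111 in the other pairs. Counts of changed genes are therefore also given without this library, which lowered the common dispersion of the edgeR fit from 0.0474 to 0.0115. Leaving out its replicate instead keeps this library as the only control of day 3 and also takes the spread of the pair out of the fit. Calls gained or lost in that setting rest on this library.

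Averaged over days 0, 3 and 5, the libraries labelled knockdown had lower levels of several genes of the mineralising osteoblast. Alpl (ENSMUSG00000028766.8, chromosome 4, 137741733 to 137796384, GRCm38), the alkaline phosphatase that frees phosphate for mineral, stood at 2.71 ± 0.192, 110 ± 14.4 and 153 ± 4.44 CPM (SD, n = 2) in control at days 0, 3 and 5 and at 0.213 ± 0.00603, 18.9 ± 1.82 and 43.3 ± 2.96 CPM in the libraries labelled knockdown. Its mean log2 fold change was −2.66 (SE 0.13, adjusted p = 6.78e-07), with 4 and 3 counts in the libraries labelled knockdown at day 0. Ibsp (ENSMUSG00000029306.8, chromosome 5, 104299171 to 104311469, GRCm38), a bone matrix sialoprotein that nucleates mineral, stood at 12.3 ± 3.34, 1100.5 ± 87.8 and 7836 ± 789 CPM in control. The libraries labelled knockdown held 2.09 ± 0.882, 82.9 ± 13.3 and 373 ± 33.1 CPM, a mean log2 fold change of −3.57 (SE 0.18, adjusted p = 1.21e-06). Runx2 (ENSMUSG00000039153.14, chromosome 17, 44495987 to 44814797, GRCm38), the transcription factor that commits cells to the osteoblast lineage, fell by 0.61 on the log2 scale (SE 0.10, adjusted p = 0.00208). All 6 libraries labelled knockdown lay below both control libraries of their day for each of these 3 genes.

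**Figure D2:**
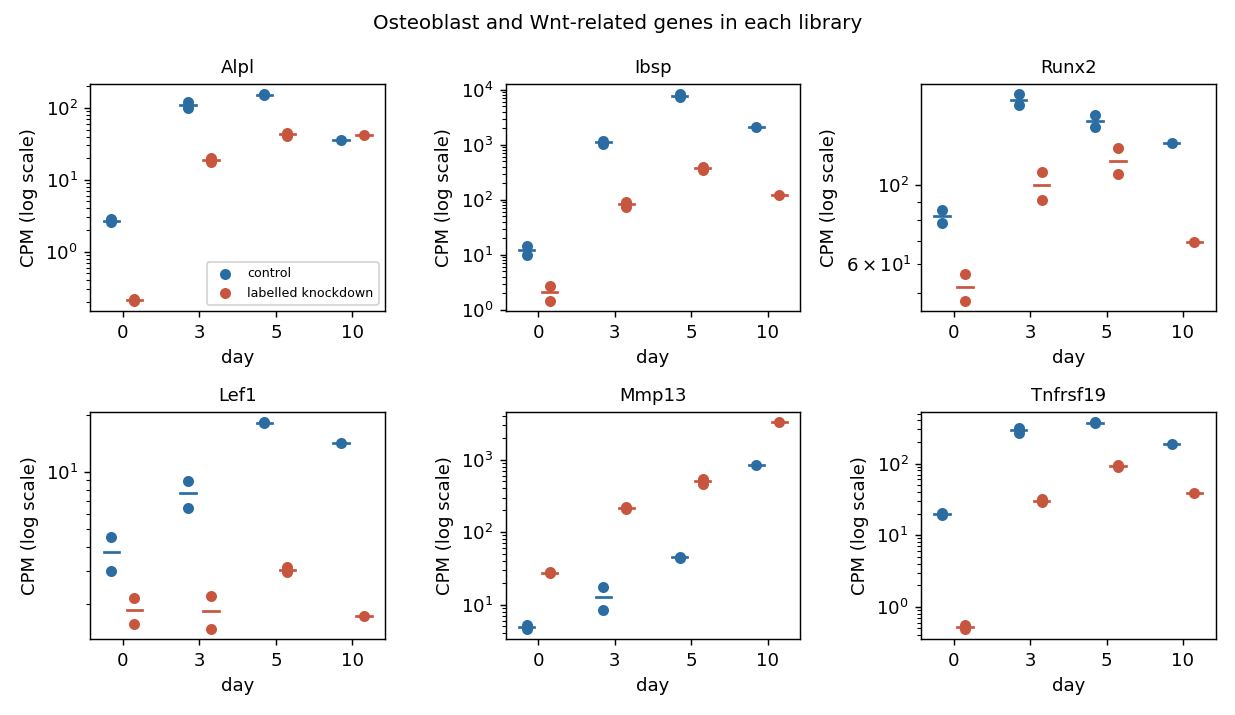
Levels of Alpl, Ibsp, Runx2, Lef1, Mmp13 and Tnfrsf19 in each library, in CPM on a log scale (vertical axes) by day (horizontal axes). Points are libraries and bars are group means, with 2 libraries per group at days 0, 3 and 5 and 1 at day 10. Ibsp reached 7836 CPM in control and 373 CPM in the libraries labelled knockdown at day 5, while Alpl at day 10 was 35.6 and 41.5 CPM.

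Other differentiation genes moved in both directions. Of 24 measured genes of the mature osteoblast, 8 rose, 11 fell and 5 did not pass, and adjusted over the list alone 9 rose and 11 fell; camera called the list lower (adjusted p = 0.00336; adjusted p = 0.153 with an estimated correlation). Tnc, a matrix glycoprotein of bone surfaces, fell by 1.68 on the log2 scale (SE 0.14, adjusted p = 2.64e-05), and Cthrc1, a secreted protein of bone-forming cells, fell by 4.32 (SE 0.25, adjusted p = 2.86e-06). Spp1, a matrix phosphoprotein, had an averaged rise of 0.60 (SE 0.14, adjusted p = 0.012) made of log2 fold changes of 1.10 and 1.44 at days 0 and 3 and −0.74 at day 5. With day 3 left out the value was 0.18 (adjusted p = 0.124). Bglap, the osteocalcin gene, may share reads with near-identical copies and is uncertain; its level was 0.349 ± 0.13 CPM in control and 4.70 ± 0.147 CPM in the libraries labelled knockdown at day 3 and 1.24 ± 0.0128 and 9.24 ± 0.223 CPM at day 5. The averaged rise of Bglap (adjusted p = 0.00873) was lost without knockdown day 0 replicate 1 (adjusted p = 0.944) and without day 3 (adjusted p = 0.086). Of 19 osteoblast transcription factors, 2 rose and 6 fell, as they did adjusted over the list alone, and camera did not call the list (adjusted p = 0.0568); 4 rose and 9 fell without control day 3 replicate 2. Mef2c, a factor that acts in late osteoblasts and osteocytes, fell by 1.43 (SE 0.13, adjusted p = 4.72e-05). Sp7, the zinc-finger factor that acts downstream of Runx2, had a log2 fold change of −0.28 (SE 0.13, adjusted p = 0.132), and passed with day 3 or control day 3 replicate 1 left out (−0.26 and −0.35, adjusted p = 0.0391 and 0.0046).

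Osteocyte genes also moved in both directions. Of 11 measured, 4 rose, 2 fell and 5 did not pass (4 and 3 adjusted over the list alone). Camera called the list higher (adjusted p = 0.0312; adjusted p = 0.223 with an estimated correlation), a call lost without control day 0 replicate 1 (adjusted p = 0.056) or control day 3 replicate 1 (adjusted p = 0.14). Phex, an endopeptidase of osteocytes that acts in phosphate balance, was 0.471 ± 0.219, 1.18 ± 0.422 and 1.79 ± 0.548 CPM in control and 3.14 ± 0.375, 25.3 ± 2.93 and 23.9 ± 1.65 CPM in the libraries labelled knockdown, a log2 fold change of 3.59 (SE 0.20, adjusted p = 1.89e-06). Ackr3, a scavenger receptor for the chemokine Cxcl12, rose by 1.63 on the log2 scale (SE 0.16, adjusted p = 7e-05), and Pdpn, a membrane protein of early osteocytes, rose by 0.63 (SE 0.11, adjusted p = 0.0022). Dmp1, a matrix protein of osteocytes, had an averaged rise of 1.38 (SE 0.14, adjusted p = 9.4e-05) that did not hold at every day. It stood at 13.1 ± 1.97 CPM in control and 117 ± 15.1 CPM in the libraries labelled knockdown at day 0, and at 124 ± 6.53 and 70.3 ± 7.18 CPM at day 5 (−0.82, adjusted p = 0.0657).

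Matrix genes were counted on 3 lists. Of 39 collagens and collagen-modifying enzymes, 4 rose, 18 fell and 17 did not pass (4 and 19 adjusted over the list alone; camera adjusted p = 0.000201; adjusted p = 0.227 with an estimated correlation). Adamts2, which trims procollagen, fell by 1.98 (SE 0.10, adjusted p = 7.63e-07), P4ha2, a prolyl hydroxylase of collagen, by 1.24 (SE 0.09, adjusted p = 7.61e-06), and Loxl1, a cross-linking oxidase, by 1.34 (SE 0.10, adjusted p = 1.21e-05). Col18a1, a basement membrane collagen, rose by 1.28 (SE 0.10, adjusted p = 1.07e-05). Col1a1, the main collagen chain of bone, stood at 4141 and 4877 CPM in control at day 0. The libraries labelled knockdown held 2561 and 2728 CPM, while at day 5 the values were 6454 and 7200 against 6048 and 6264 CPM. The averaged log2 fold change of Col1a1 was −0.29 (SE 0.12, adjusted p = 0.103). It passed with the replicate number as a block (−0.28, adjusted p = 0.0451), without day 3 (−0.46, adjusted p = 0.00174), and without control day 3 replicate 1 or 2 (adjusted p = 0.002 and 0.0222). Among 32 proteoglycans and other matrix proteins 7 rose and 12 fell (7 and 14 adjusted over the list alone; camera adjusted p = 0.00336; adjusted p = 0.319 with an estimated correlation). Fmod, a small proteoglycan that binds collagen fibrils, fell by 2.07 (SE 0.10, adjusted p = 9.2e-07) and Nid1, a basement membrane protein, by 3.33 (SE 0.20, adjusted p = 3.47e-06). Of 21 matrix proteases and inhibitors 9 rose and 5 fell (11 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0715; adjusted p = 0.0206 without control day 3 replicate 2). Mmp13, a collagenase of bone, stood at 4.95 ± 0.475, 12.8 ± 6.31 and 45.1 ± 1.05 CPM in control and 27.6 ± 0.844, 214 ± 7.32 and 501 ± 53.5 CPM in the libraries labelled knockdown, a log2 fold change of 3.33 (SE 0.17, adjusted p = 1.33e-06).

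Wnt genes were the subject of the series' question. Of 28 measured targets of canonical Wnt signalling, 7 rose, 9 fell and 12 did not pass, and adjusted over the list alone 7 rose and 11 fell. Camera called the list lower in the libraries labelled knockdown (adjusted p = 0.00336; adjusted p = 0.252 with an estimated correlation), a call lost without control day 3 replicate 1 (adjusted p = 0.081). Lef1 (ENSMUSG00000027985.12, chromosome 3, 131110471 to 131224356, GRCm38), which encodes a DNA-binding partner of beta-catenin, was 3.77 ± 1.10, 7.70 ± 1.75 and 18.1 ± 0.178 CPM in control and 1.87 ± 0.411, 1.85 ± 0.523 and 3.05 ± 0.15 CPM in the libraries labelled knockdown, a log2 fold change of −1.88 (SE 0.18, adjusted p = 5.68e-05). Axin2, a feedback inhibitor of the pathway, fell by 0.84 (SE 0.18, adjusted p = 0.00808), and limma on log2(RPKM + 1) gave it an adjusted p of 0.067. Tnfrsf19, a receptor of the tumour necrosis factor family, fell by 3.50 (SE 0.11, adjusted p = 8.75e-08) and Myc, a growth regulator, by 0.997 (SE 0.16, adjusted p = 0.00139). Ccnd1, which encodes the cyclin of early G1 and stands on the same list, rose by 0.60 (SE 0.10, adjusted p = 0.00143). Tcf7, a close relative of Lef1, was 7.43 ± 0.723 CPM in control and 0.525 ± 0.207 CPM in the libraries labelled knockdown at day 5. Its averaged fall (adjusted p = 0.0211) was lost without control day 0 replicate 2 (adjusted p = 0.972) or knockdown day 0 replicate 1 (adjusted p = 0.0551).

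Components of the Wnt pathway were measured as well. Ctnnb1, which encodes beta-catenin, had a log2 fold change of −0.32 (SE 0.12, adjusted p = 0.0662), which passed with the replicate block (adjusted p = 0.0408), without day 3 (adjusted p = 0.00138), and without control day 3 replicate 1 or 2 (adjusted p = 0.00703 and 0.000172). Of 40 ligands, receptors and intracellular components 5 rose and 8 fell, as they did adjusted over the list alone (camera adjusted p = 0.555; 10 and 12 without control day 3 replicate 2). Wnt5b, a ligand that mostly signals without beta-catenin, fell by 2.57 (SE 0.23, adjusted p = 3.89e-05) and Fzd6, a receptor, rose by 1.08 (SE 0.18, adjusted p = 0.00214). Among 10 secreted antagonists 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.832). Dkk3 and Igfbp4 rose by 0.78 and 0.95 (SE 0.10 and 0.12, adjusted p = 0.000426 and 0.000437). Sfrp2 had an averaged fall of 1.43 (SE 0.11, adjusted p = 9.6e-06) made of log2 fold changes of −3.31, −0.74 and −0.24 at days 0, 3 and 5. Of 23 nuclear repressors of Wnt and Runx2 activity 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.819; 8 and 4 without control day 3 replicate 2). The log2 fold changes of Tcf12 and E2f6, 2 repressors named beforehand, were −0.02 (SE 0.13, adjusted p = 0.937) and 0.31 (SE 0.17, adjusted p = 0.211). Without control day 3 replicate 1, which leaves replicate 2 as the only control of day 3, they were 0.13 and 0.55. In all, 5 other settings also turned the sign of Tcf12.

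Camera also called some lists of signalling, growth and metabolism, each of which lost its call with an estimated correlation. Of 30 genes of BMP and TGF-beta signalling 2 rose and 8 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.000682; adjusted p = 0.227 with an estimated correlation; 4 and 15 without control day 3 replicate 2). Bmp4, a bone-inducing ligand, fell by 2.50 (SE 0.10, adjusted p = 1.97e-07) and Grem1, a BMP antagonist, by 1.83 (SE 0.12, adjusted p = 3.74e-06). Among 31 genes of glycolysis and the hypoxia response 3 rose and 14 fell (4 and 19 adjusted over the list alone; camera adjusted p = 0.00336; adjusted p = 0.153 with an estimated correlation), with Hk2, which phosphorylates glucose, lower by 1.53 (SE 0.10, adjusted p = 4.98e-06). Of 20 NRF2 and glutathione genes 6 rose and 0 fell by edgeR's adjusted p (7 and 1 adjusted over the list alone; camera adjusted p = 0.0248; adjusted p = 0.223 with an estimated correlation; 9 and 3 without control day 3 replicate 2). Nqo1, a quinone reductase induced by NRF2, rose by 2.38 (SE 0.11, adjusted p = 6.78e-07). Camera also called the 35 genes of DNA replication lower (0 rose and 5 fell, also adjusted over the list alone; adjusted p = 0.0387; adjusted p = 0.223 with an estimated correlation), and without control day 3 replicate 2 the count was 0 and 14. Tyms, which makes thymidylate, fell by 0.81 (SE 0.12, adjusted p = 0.000819). That list lost its call without control day 3 replicate 1 (adjusted p = 0.081) or knockdown day 0 replicate 1 (adjusted p = 0.052). Of 35 mitotic genes 1 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.0387; adjusted p = 0.678 with an estimated correlation; 1 and 24 without control day 3 replicate 2). The mitotic call was lost without control day 0 replicate 1 (adjusted p = 0.056) or control day 3 replicate 1 (adjusted p = 0.51). Birc5, a subunit of the chromosomal passenger complex, fell by 0.69 (SE 0.14, adjusted p = 0.00517).

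The 10 largest rises and falls chosen by size included genes with few counts in the replicated control groups. Angpt1, a ligand of the endothelial Tie2 receptor, was at most 0.220 ± 0.312 CPM in the replicated control groups and 4.36 ± 1.02, 26.8 ± 3.83 and 30.5 ± 1.11 CPM in the libraries labelled knockdown at days 0, 3 and 5. Krt9, a keratin of palm and sole skin, was at most 0.285 ± 0.221 CPM in those groups and 17.6 ± 1.03, 12.3 ± 2.06 and 11.4 ± 3.32 CPM. Pid1, a protein that binds lipoprotein receptors, rose by 4.04 on the log2 scale (SE 0.12, adjusted p = 8.75e-08), and Itgbl1, Syt1, Cst6, Sybu, Epb4.1l4b, Adam8 and Csgalnact1 were the other 7 of the 10 largest rises. The largest fall was that of Igfbp2, an insulin-like growth factor binding protein, by 4.92 (SE 0.21, adjusted p = 4.38e-07), and it was followed by Cthrc1, Il1rn, Ibsp, Tnfrsf19, Grb14, Nid1, Panx3, Crip1 and Mest. Mest, an imprinted gene, fell by 2.96 (SE 0.10, adjusted p = 1.45e-07). In all 6 libraries labelled knockdown the levels of these 20 genes lay on the same side of both control libraries of their day, except Panx3, for which this held at 2 of the 3 days. The genes were chosen by their differences in these same libraries, so that this adds no support.

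Measures of RNA composition also differed with the labels. Of 75 cytoplasmic ribosomal protein genes 0 rose and 54 fell by edgeR's adjusted p (0 and 70 adjusted over the list alone; camera adjusted p = 7.33e-13; adjusted p = 0.556 with an estimated correlation). At single days 0, 59 and 0 of them fell at days 0, 3 and 5, and without control day 3 replicate 2 the averaged count was 64, with 34, 42 and 46 at days 0, 3 and 5. Of 15 mitochondrially encoded transcripts 6 rose and 0 fell by edgeR's adjusted p, also adjusted over the list alone (camera adjusted p = 0.0196; adjusted p = 0.223 with an estimated correlation). All genes of the mitochondrial chromosome together, a larger set than the list, took 3.46% to 5.00% of the counts in the libraries labelled knockdown and 1.91% to 3.09% in control. Of 43 nuclear genes of oxidative phosphorylation 0 rose and 10 fell by edgeR's adjusted p (0 and 9 adjusted over the list alone; camera adjusted p = 0.00451; adjusted p = 0.694 with an estimated correlation). That call was lost without control day 3 replicate 2 (adjusted p = 0.106; 5 rose and 15 fell).

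In total, 3530 of 13130 genes tested differed between the conditions averaged over days 0, 3 and 5, 1968 higher and 1562 lower in the libraries labelled knockdown (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1159 of them at least 2-fold. The direction was the same at days 0, 3 and 5 for 3292 of the 3530 (93.3%) and at all 4 days for 3081 (87.3%). These genes were called on the average of days 0, 3 and 5, which makes agreement at those days likely. With library size as the only scaling the count was 3344, 2209 higher and 1135 lower. Without control day 3 replicate 2 the count was 6168, of which 3520 were shared, without control day 3 replicate 1 it was 7604, and leaving out any 1 of the other 10 libraries gave 2389 to 2540. Of the 38 fixed lists, camera called 15; with an estimated correlation it called 0 (8 at an unadjusted p under 0.05), and fry, which asks only whether a list's genes move one way on balance, called 28. A list's median, mean and test differed in sign only in lists that camera did not call, such as the Wnt ligands and receptors, with a median of 0.08 and a test direction of lower.

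The days were also compared singly. At day 0, 931 genes differed (579 higher and 352 lower in the libraries labelled knockdown). Krt14, a keratin of basal epidermis, stood at 0.563 ± 0.00885 CPM in control and 44.0 ± 3.08 CPM in those libraries, a log2 fold change of 6.27 (SE 0.40, adjusted p = 1.77e-05). At day 3, 1652 genes differed (927 higher and 725 lower), led on the falling side by Igfbp2 and by Panx3, a channel protein of osteoblasts and chondrocytes (−5.06 and −4.45; SE 0.36 and 0.48, adjusted p = 7.46e-05 and 0.000531). At day 5, 1022 genes differed (698 higher and 324 lower), among them Col11a2, a cartilage collagen chain, and H19, an imprinted noncoding RNA (−6.93 and −6.05; SE 0.28 and 0.36, adjusted p = 4.16e-06 and 3.76e-05). Effects at days 0 and 5, which share no library, correlated at 0.57 across genes (genes are not independent replicates); 311 genes were higher at both days (30.8 for independent lists) and 108 lower at both (8.69). Leaving out control day 3 replicate 2 gave 3742, 2745 and 4118 genes at days 0, 3 and 5, leaving out its replicate gave 3742, 7718 and 4103, and leaving out any 1 of the other 10 libraries gave 367 to 697, 358 to 925 and 338 to 759. A fit of the 4 day 3 libraries alone called 0 genes with edgeR (1466 at an unadjusted p under 0.05; DESeq2 on all 14 libraries called 2804), and Igfbp2 and Panx3 then had an adjusted p of 0.0929. With the replicate number as a block within the day the counts were 6443, 375 and 6538. Those fits held only the 4 libraries of a day and left few residual degrees of freedom. Library size alone as scaling gave 1087 higher and 433 lower at day 3, where it moved the median log2 fold change of all genes from 0.01 to 0.18. Every call of days 0 and 5 was kept without control day 3 replicate 2, but part of the 1652 calls of day 3 was not.

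At day 10 each condition had 1 library, so the difference had no replicate check. With the spread taken from the other groups and the lone libraries assumed to vary like them, 253 genes differed (189 higher and 64 lower in the library labelled knockdown; 2034 and 2059 without control day 3 replicate 1 or 2, and 142 to 191 without any 1 of the other 10 replicated libraries). In these libraries Ibsp stood at 2064.4 CPM in control and 123 CPM in the one labelled knockdown, Lef1 at 14.1 and 1.74 CPM, Mmp13 at 835 and 3287.5 CPM, and Alpl at 35.6 and 41.5 CPM. The median log2 difference of the mature osteoblast list was 0.06, at percentile 74.7 of 10000 random lists of the same size matched on expression. Mitotic genes had a median of −0.83 and replication genes of −0.39, both at percentile 0, while matrix proteases and proteoglycans had medians of 0.46 and 0.38, both at percentile 100. Lists of RNA composition lay as far out in the same libraries, mitochondrially encoded transcripts with a median of 1.26 (percentile 100) and cytoplasmic ribosomal proteins of −0.43 (percentile 0). So did lists of other kinds, with tendon and fibroblast markers at 0.71 and the unfolded protein response at 0.38 (both at percentile 100), and muscle and myeloid markers at 0.79 and 1.33 (both at percentile 99.4). Canonical Wnt targets lay at percentile 46.9, with a median of −0.03, and Wnt ligands and receptors at percentile 47.0. Secreted Wnt antagonists and nuclear repressors of Wnt and Runx2 lay at percentiles 98.5 and 99.7, with medians of 0.86 and 0.23. Spectraplakins and microtubule plus-end proteins lay at percentile 0.21, with a median of −0.31. These percentiles describe these libraries only.

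Control cells changed strongly between day 0 and day 5, the course against which the series sets MACF1. Genes of the mature osteoblast rose: 14 of 24 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 8.27e-27). Ibsp rose by 9.31 on the log2 scale (SE 0.39, adjusted p = 1.49e-06) and Alpl by 5.81 (SE 0.21, adjusted p = 9.69e-07). Also rising were Phospho1, a phosphatase of matrix vesicles, by 7.27 (SE 0.39, adjusted p = 8.93e-06), and Pth1r, the parathyroid hormone receptor, by 6.80 (SE 0.48, adjusted p = 4.41e-05). Col11a2 rose by 8.09 (SE 0.31, adjusted p = 1.09e-06), H19 went from 0.484 ± 0.389 to 493 ± 71.8 CPM, and Ncf1, a subunit of the phagocyte NADPH oxidase, from 0 counts in both libraries to 42.6 ± 5.60 CPM. Il1rn, an antagonist of interleukin 1, fell by 4.61 (SE 0.36, adjusted p = 7.11e-05), and Otor, Enpep, Aoc3 and Npr3 fell by 3.41 to 4.56. For each of these genes both day 5 libraries lay on the same side of both day 0 libraries, which their choice from these libraries makes likely.

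Canonical Wnt targets rose with time in control, 10 of 28 rising and 3 falling (14 and 5 adjusted over the list alone; camera adjusted p = 5.83e-10; 16 and 7 without control day 3 replicate 2). Wif1, a secreted Wnt inhibitor that is itself a target, rose by 6.39 (SE 0.33, adjusted p = 7.58e-06), Tnfrsf19 by 4.23 (SE 0.18, adjusted p = 1.49e-06) and Lef1 by 2.26 (SE 0.29, adjusted p = 0.00135). Glycolysis and hypoxia genes rose, 15 of 31 rising and 0 falling by edgeR's adjusted p (21 and 0 adjusted over the list alone; camera adjusted p = 4.61e-12; 24 and 1 without control day 3 replicate 2), among them Car9, a carbonic anhydrase induced by hypoxia, by 6.10 (SE 0.34, adjusted p = 8.93e-06). Of 25 immediate early genes 9 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 1.64e-08), and 16 and 2 without control day 3 replicate 2. Egr1, a transcription factor induced by serum, rose by 2.48 (SE 0.18, adjusted p = 4.7e-05). Of 22 cholesterol synthesis genes 0 rose and 14 fell by edgeR's adjusted p (0 and 20 adjusted over the list alone; camera adjusted p = 9.98e-17; 1 and 21 without control day 3 replicate 2), among them Sqle, the squalene epoxidase, by 1.41 (SE 0.21, adjusted p = 0.0026). Of 43 interferon-stimulated genes 1 rose and 11 fell (1 and 24 adjusted over the list alone; camera adjusted p = 6.88e-11; 1 and 31 without control day 3 replicate 2), with Ifit3 lower by 2.05 (SE 0.30, adjusted p = 0.00263).

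Other lists also moved in control between day 0 and day 5. Of 21 targets of YAP and SRF 0 rose and 7 fell (0 and 8 adjusted over the list alone; camera adjusted p = 1.72e-05; 1 and 13 without control day 3 replicate 2). Acta2, an actin of contractile cells, fell by 1.70 (SE 0.21, adjusted p = 0.00102). Of 20 NRF2 and glutathione genes 0 rose and 4 fell (0 and 6 adjusted over the list alone; camera adjusted p = 0.00012; 1 and 8 without that library), Gsta4 by 3.20 (SE 0.25, adjusted p = 6.01e-05). Of 20 p53 targets 4 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00405; 12 and 1 without that library). Of 13 chondrocyte markers 4 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 2.02e-06; 5 and 2 without that library), Col2a1 by 1.72 (SE 0.17, adjusted p = 0.000235). Of 35 genes of G2 and mitosis 6 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 2.02e-06; adjusted p = 0.254 with an estimated correlation; 25 and 0 without control day 3 replicate 2). Cenpe, a kinesin of the kinetochore, rose by 1.31 (SE 0.19, adjusted p = 0.00251). Of 11 osteoclast coupling factors 1 rose and 6 fell (1 and 8 adjusted over the list alone; camera adjusted p = 2.94e-05; adjusted p = 0.159 with an estimated correlation). The member that rose was Tnfrsf11b, the decoy receptor of RANKL (5.03, SE 0.65, adjusted p = 0.00135).

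Camera called 16 lists between control days 0 and 5 and 10 with an estimated correlation: mature osteoblast, Wnt targets, YAP and SRF targets, interferon, p53, NRF2, immediate early, hypoxia, cholesterol and chondrocyte genes. In total 1068 genes differed between the days, 567 higher and 501 lower at day 5. The count was 4122 without control day 3 replicate 2 and 4124 without control day 3 replicate 1, libraries that enter this comparison only through the shared spread, and 333 to 762 without any 1 of the other 10. From day 0 to day 3, 1411 genes differed in control (695 higher and 716 lower; 3394 without control day 3 replicate 2, 7183 without replicate 1, and 197 to 918 without any 1 of the other 10). From day 0 to the single day 10 library the count was 713 (427 and 286; 3445 and 3451 without control day 3 replicate 1 or 2, and 246 to 477 without any 1 of the other 10). These comparisons share the control libraries of day 0, so their overlaps were not compared.

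The libraries labelled knockdown also gained osteoblast genes from day 0 to day 5. Alpl went from 4 and 3 counts to 43.3 ± 2.96 CPM (adjusted p = 3.6e-07). Ibsp rose by 7.50 on the log2 scale (adjusted p = 6.33e-06), Pth1r by 5.53 and Tnfrsf19 by 7.46, both day 5 libraries lying above both day 0 libraries. Of the 24 mature osteoblast genes 11 rose and 0 fell by edgeR's adjusted p (camera adjusted p = 7.02e-38; adjusted p = 0.000244 with an estimated correlation; 13 and 4 without control day 3 replicate 2), and cholesterol synthesis genes were called lower (adjusted p = 2.66e-17; 0.00132 with an estimated correlation). H19 reached 199 CPM in the library labelled knockdown at day 10, against 1282 CPM in control. From day 0 to day 5 its log2 fold change was 0.16 (adjusted p = 0.933) and that of Col11a2 was 1.13 (adjusted p = 0.121). In total 262 genes differed (190 higher and 72 lower), with 2028 and 2032 without control day 3 replicate 1 or 2 and 36 to 167 without any 1 of the other 10 libraries. The time courses of the conditions share no library and correlated at 0.43 across genes (genes are not independent replicates); 100 genes rose in both (8.20 for independent lists), 39 fell in both (2.75), and 13 moved in opposite directions.

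Genes of whole chromosomes were displaced together between the conditions, a comparison added after the results were seen. Averaged over days 0, 3 and 5, the median log2 fold change was 0.42 over the genes of chromosome 15, of which 82.2% lay above 0, 0.34 over those of chromosome 3 (77.0%) and 0.23 over those of chromosome 10 (71.4%). It was −0.26 on chromosome 5, with 24.3% above 0, and between −0.19 and −0.21 on chromosomes 2, 6, 9 and 13. On chromosome 15, 226 genes were called higher in the libraries labelled knockdown and 20 lower, on chromosome 10, 161 and 24, and on chromosome 5, 60 and 247. Between control days 0 and 5 no chromosome from 1 to 19 or X had a median beyond 0.081. With each chromosome's median removed, 2681 genes differed averaged over the days, of which 2379 were among the 3530. Among the results of named genes 21 lost the threshold, 1 gained it and 1 reversed. No gene whose averaged change is given above as passing was among the 21. The gain was that of Sp7, which lies on chromosome 15 (log2 fold change −0.70, adjusted p = 0.00361).

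**Figure D3:**
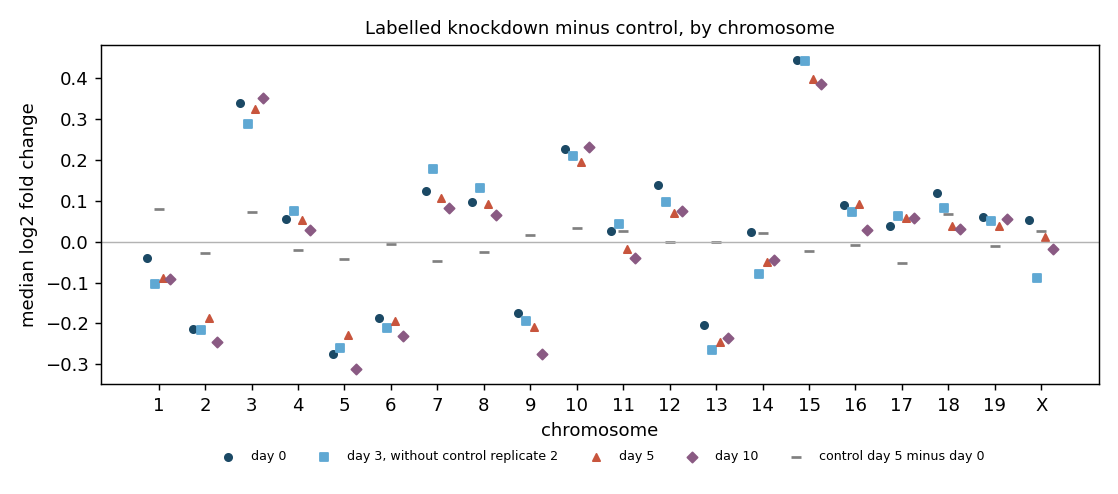
Median log2 fold change (vertical axis) of the genes of each chromosome (horizontal axis), libraries labelled knockdown minus control, at day 0, day 3 without control replicate 2, day 5 and day 10, with control day 5 minus day 0 as dashes. Chromosome 15 lay at 0.39 to 0.45 at the 4 days and at −0.02 between the control days.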

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

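No test of the differences between days was chosen after its result was seen. The joint edgeR quasi-likelihood test with Benjamini-Hochberg adjustment asked whether the difference between the libraries labelled knockdown and control varied between days 0, 3 and 5, and it passed for 131 of 13130 genes. The count was 1126 without control day 3 replicate 2, 6510 without control day 3 replicate 1, and 43 to 66 without any 1 of the other 10 libraries. The values below are the log2 fold change at day 5 minus that at day 0, for the 10 genes with the smallest p.

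H19, an imprinted noncoding RNA, had the smallest p. Its fitted difference of −9.78 (adjusted p = 0.000315) depends on the 12 and 3 counts of control at day 0 and is not a measured size. It stood at 0.484 ± 0.389 CPM in control and 6.63 ± 0.163 CPM in the libraries labelled knockdown at day 0, and it reached 493 ± 71.8 CPM (SD, n = 2) in control at day 5 and 7.46 ± 1.33 CPM in the libraries labelled knockdown. Col11a2, a cartilage collagen chain, differed by −6.96 (adjusted p = 0.000342), with log2 fold changes of 0.03, −2.78 and −6.93 at days 0, 3 and 5. Sfrp2, a secreted modulator of Wnt signalling, differed by 3.07 (adjusted p = 0.00117), from −3.31 at day 0 to −0.24 at day 5; control held 1266.4 ± 1.24 CPM at day 0 and 209 ± 6.23 CPM at day 5, while the libraries labelled knockdown held 128 ± 12.4 and 177 ± 10.0 CPM. Npnt, a ligand of integrin alpha 8 beta 1, differed by 3.61 (adjusted p = 0.000692), from −3.05 to 0.56.

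Other genes were higher in the libraries labelled knockdown at day 0 and near or below control at day 5. Krt14 differed by −6.04 (adjusted p = 0.00117), from 6.27 to 0.23. Prss35, a secreted protein related to serine proteases, differed by −5.56 (adjusted p = 0.00105), from 5.46 to −0.09. Lrrc15, a membrane protein of osteoblasts and stromal cells, differed by −4.53 (adjusted p = 0.00129), from 4.07 to −0.46. Anxa8, an annexin, differed by −3.42 (adjusted p = 0.000342), from 1.90 to −1.52, and Dtx4, a member of the deltex family, by −3.41 (adjusted p = 0.00117), from 1.70 to −1.71. Klf4, a transcription factor that restrains proliferation, differed by −2.90 (adjusted p = 0.00117), from 2.42 to −0.48. No explanation was tested for these differences.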

How the results depend on the processing

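Leaving out day 3, removing chromosome medians and removing a trend with gene length were chosen after the results were seen. For the genes named, 303 results gave 8310 alternative values: 7899 kept their direction and their side of the threshold, 378 lost the threshold, 23 gained it and 10 reversed. The reversals were of Macf1 and Tcf12, neither of which passed in the fit of all libraries. Macf1 was −0.053 over all 4 days, −0.047 without day 3 and −0.050 with the length trend removed. Leaving out a library gave −0.081 (control day 3 replicate 2) to 0.51 (control day 3 replicate 1). Tcf12 was 0.060 with library size only, 0.0027 without a filter, and 0.090 and 0.097 with limma on log2(RPKM + 1) and log2(RPKM + 0.1). It was 0.18 with chromosome medians removed, and leaving out a library gave −0.13 (control day 3 replicate 2) to 0.13 (control day 3 replicate 1). The fit without replicate 1 keeps replicate 2 as the only control of day 3. The cause was not tested.

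The 3530 genes of the average over days 0, 3 and 5 were 1159 with a 2-fold minimum, a stricter threshold by construction, and 5370 without day 3 (3248 shared). The DESeq2 Wald test gave 1469, 2804, 1607 and 578 genes at days 0, 3, 5 and 10. It gave 2578, 1679 and 1266 in control from day 0 to days 3, 5 and 10, and 612 in the libraries labelled knockdown from day 0 to day 5. The likelihood ratio test of DESeq2 gave 432 genes differing between days. Without a filter the counts were 2827 at day 3, 501 at day 10, 2538 and 1102 in control to days 3 and 10, 509 in the libraries labelled knockdown to day 5, and 643 differing between days. Only the 4 libraries of a day gave 3481, 0 (1466 at an unadjusted p under 0.05) and 3632 at days 0, 3 and 5. Lists averaged over the days numbered 15 with camera, 0 with an estimated correlation (8 at an unadjusted p under 0.05) and 28 with fry (13 shared), and lists of the control course 16 and 10. The cause was not tested.

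With the replicate number as an additive block, 3913 genes differed averaged over the days, 1114, 1864, 1277 and 308 at days 0, 3, 5 and 10, and 1756, 1345 and 793 in control to days 3, 5 and 10. There were 332 in the other course, 139 between days, and 14 and 17 lists. The block within the day gave 6443, 375 and 6538 at days 0, 3 and 5, and 3269 averaged. Each single-day fit held only the 4 libraries of that day and left few residual degrees of freedom. Calls changed by a block among named results were Col1a1 and Ctnnb1 (gained), Nav1, Ddit3 and Col9a1 (lost; adjusted p = 0.0530, 0.0529 and 0.0550). Among lists, the chondrocyte markers averaged over days were lost (adjusted p = 0.0606). In the control course the secreted Wnt antagonists were lost (adjusted p = 0.0639), and the focal adhesion and S-phase lists were gained as lower (adjusted p = 0.0180 and 0.0348). The block changed no other call among the named results or the lists of these comparisons, and lists of the other comparisons were not refitted with it. Among all genes, 3431 of the 3530 averaged calls were shared with the additive block.

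Leaving out each replicated library in turn gave 2389 to 7604 genes averaged over the days, 367 to 3742, 358 to 7718, 338 to 4118 and 142 to 2059 at days 0, 3, 5 and 10. It gave 197 to 7183, 333 to 4124 and 246 to 3451 in control to days 3, 5 and 10, 36 to 2032 in the other course, 43 to 6510 between days, and 11 to 15 and 14 to 20 lists. The highest gene counts all came without a library of the control pair of day 3, whose difference sets much of the shared spread: the common dispersion fell from 0.0474 to 0.0115 without replicate 2. Genes near 1 CPM rest on few counts. In simulated counts 2-fold changes were recovered in 17% to 18% of the changed genes at days 0, 3 and 5 singly and in 2% at day 10. The lowest genes tested were not among those changed.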

Other observations

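The tests of a hidden fall of Macf1, of a loss of long transcripts, of noise between libraries and of chromosome content were chosen after their results were seen. Lists not yet described were also compared between the conditions averaged over days 0, 3 and 5, and of the next 5 camera called only the tubulins. Of 43 interferon-stimulated genes 11 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.215; 19 and 6 without control day 3 replicate 2). Mx1, a GTPase that blocks viral replication, was 0.423, 0.161 and 0.134 CPM in control at days 0, 3 and 5 and 4.09, 2.67 and 4.45 CPM in the libraries labelled knockdown. Psmb8, an immunoproteasome subunit, fell by 1.18 on the log2 scale (SE 0.20, adjusted p = 0.00181 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 22 NF-kB and cytokine genes 6 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.515; 11 and 5 without control day 3 replicate 2). Vcam1, an adhesion molecule, rose by 0.98 (SE 0.18, adjusted p = 0.00388). Of 32 focal adhesion genes 10 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0885; 13 and 9 without that library). Tns1, which ties integrins to actin, rose by 1.87 (SE 0.11, adjusted p = 2.84e-06). Of 27 spectraplakins and microtubule plus-end proteins 3 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.832; 5 and 10 without that library). Their median of −0.06 turned to 0.02 under scaling by library size only. Of 17 tubulins 0 rose and 4 fell by edgeR's adjusted p, also adjusted over the list alone (camera adjusted p = 0.0312; adjusted p = 0.556 with an estimated correlation; 3 and 4, adjusted p = 0.118, without that library). Tubb2b fell by 2.29 (SE 0.21, adjusted p = 5.02e-05). At single days camera called focal adhesion genes higher at day 3 (adjusted p = 0.00539; adjusted p = 0.454 with an estimated correlation) and interferon-stimulated genes higher at day 5 (adjusted p = 0.00187; adjusted p = 0.103 with an estimated correlation).

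Of the remaining signalling and stress lists camera called none averaged over the days. Of 10 Notch genes 1 rose and 4 fell, and Rbpj, the DNA-binding partner of the Notch intracellular domain, rose by 1.16 (SE 0.15, adjusted p = 0.00045). Rises and falls were 1 and 1 of 8 Hedgehog genes, 7 and 2 of 21 YAP and SRF targets, 1 and 4 of 11 osteoclast coupling factors, and 4 and 3 of 27 genes of the unfolded protein response. They were 4 and 4 of 20 p53 targets, 7 and 5 of 25 immediate early genes and 4 and 3 of 22 cholesterol synthesis genes. In this order the camera adjusted p values were 0.136, 0.717, 0.164, 0.361, 0.915, 0.832, 0.932 and 0.906. Without control day 3 replicate 2 the counts were 2 and 3 for Hedgehog genes, 11 and 4 for YAP and SRF targets, 2 and 6 for osteoclast coupling factors, 8 and 4 for the unfolded protein response and 9 and 6 for cholesterol synthesis. They were 6 and 6 for p53 targets and 8 and 9 for immediate early genes. At single days it called YAP and SRF targets lower at day 0 (0 rose and 4 fell; adjusted p = 0.0124; adjusted p = 0.144 with an estimated correlation; 2 and 11 without that library). At days 3 and 5 it called them higher (7 and 1, and 8 and 0; adjusted p = 0.0106 and 0.000695; adjusted p = 0.26 and 0.0533 with an estimated correlation). Osteoclast coupling factors were called lower at day 0 (0 rose and 5 fell; adjusted p = 0.000408; adjusted p = 0.243 with an estimated correlation). Immediate early genes were called higher at day 0 (6 rose and 3 fell; adjusted p = 0.0454; adjusted p = 0.145 with an estimated correlation), a call lost without control day 3 replicate 2 (10 and 5; adjusted p = 0.0569). Markers of other cell types were also counted. Chondrocyte markers were called lower (1 rose and 4 fell of 13, also adjusted over the list alone; camera adjusted p = 0.0343; adjusted p = 0.249 with an estimated correlation), a call lost without control day 0 replicate 1, control day 3 replicate 1 or control day 3 replicate 2 (adjusted p = 0.0564, 0.107 and 0.0867). Sox6, a chondrocyte transcription factor, fell by 2.33 (SE 0.24, adjusted p = 0.000109). By edgeR's adjusted p, muscle markers rose in 7 and fell in 2 of 12, tendon and fibroblast markers in 6 and 3 of 14, adipocyte markers in 3 and 1 of 11, and myeloid markers in 2 and 0 of 6 (camera adjusted p = 0.132, 0.108, 0.928 and 0.136). Endothelial markers rose in 0 and fell in 1 of 6, and replication-dependent histones in 2 and 0 of 6 (camera adjusted p = 0.906 for each). Without control day 3 replicate 2 the counts were 3 and 1 for endothelial, 6 and 6 for tendon and fibroblast and 3 and 3 for adipocyte markers. Cd34 and Ly6a, surface proteins of stromal progenitors, rose by 1.42 and 1.97 (SE 0.09 and 0.18, adjusted p = 4.48e-06 and 5.15e-05).

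No fall of Macf1 in the libraries labelled knockdown passed at days 0, 3 and 5, although at day 5 its mean of 175 CPM lay below the 190 CPM of control. A 2-fold fall hidden by the low value of control day 3 replicate 2 was tested on the interval of the mean log2 fold change without that library. Its lower bound was −0.21, above the −1 that such a fall requires. Libraries swapped between the conditions were tested by whether each follows its own condition's difference at the other days. Of 14 libraries, 0 correlated negatively with it. An exchange of the conditions at every day would give the same result, so that this test can see only a partial swap. A block of translation, a loss of protein with no loss of RNA, or a knockdown specific to transcripts that hold few of the counts was not tested and stays open. So do a knockdown lost before the libraries were made and an exchange of the conditions at every day.

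Control day 3 replicate 2 differed from its replicate along exon length, from a median log2 difference of 1.08 in the decile of the shortest genes to −0.67 in that of the longest. Lower depth was tested by thinning its replicate to the same total, which gave a correlation with length of −0.0114 and so argues against depth. GC content was tested as well: at a given GC content the correlation with length was still −0.346, and at a given length that with GC was 0.331, so that GC content does not account for the whole trend. A loss of long transcripts stays open, since its only test was the correlation with length of −0.404 that defines the pattern, and per the labels' protocols RNA integrity was seen on a gel, with no value per library in the sources used here. A biological difference within 1 group at 1 day has no group in the design and was not tested.

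The displacement of whole chromosomes between the conditions is a pattern for follow-up, since it would add to differences credited to MACF1. Noise between libraries is argued against by the chromosome medians of days 0 and 5, which share no library and correlated at 0.983 over 20 chromosomes, and a trend with gene length or GC content is argued against by chromosome 15, whose median was still 0.42 after the trend was removed. A difference of the cell populations in chromosome content stays open: in windows of 50 neighbouring genes, 100% of those on chromosomes 15 and 3 had a median above 0, but these chromosomes were chosen for their high medians, so that this decides nothing. Windows above 0 were 12 of 12 on chromosome 10, and on chromosomes 2, 5, 6, 9 and 13, with negative medians, 0 of 21, 1 of 17, 2 of 12, 3 of 14 and 0 of 9. No DNA was analysed here, and an effect of MACF1 on expression along chromosomes cannot be excluded.

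Other splits of the 12 libraries of days 0, 3 and 5 within each day were tested for both averaged results. For genes, 1 of 100 splits, the real one, gave as many as its 3530, and the highest other gave 447. Among the splits that part all 6 same-numbered pairs, 29 of them drawn, that highest value was also 447. Splits parting fewer pairs reached at most 152. Every other split mixes the conditions within a day or turns them round at some day. The difference between the conditions then widens the spread or cancels, so that lower counts were likely beforehand. The splits therefore cannot decide whether chance between cultures made the difference. For lists, 8 of 100 splits gave at least the 15 called, and the highest other gave 19, so that chance cannot be excluded for the number of lists called. The 7 other splits among these 8 part the conditions at 1 to 3 of the days, and the 31 splits that mix the conditions at every day called at most 8 lists.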
